A study of Mus musculus with 18 samples.

How the data were processed

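RNA from 18 cultures of mouse follicles was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per culture, after amplification from 5 ng. The deposited table gives the signal intensity of each probe set as computed by the authors with MAS5 (version not given), on a linear scale, and the 2% trimmed mean of every array is 150. The values were used as deposited, with 16 added before taking log2, and were not normalized again. Of 45101 probe sets, 64 controls were set aside and served as quality measures. The 22518 probe sets above the 50th percentile of mean log2 intensity were tested. The array annotation gave 1 symbol to 34945 of the 45037 other probe sets, several to 932 and none to 9160.

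The arrays were grouped by AMH dose (vehicle, 50 or 200 ng/mL) and time (12 or 24 h), with 3 arrays per group. The description of the 12 h AMH samples gives 24 h, while their titles and source give 12 h, and 12 h was used. The 3 doses of 1 replicate number and time came from 1 pool of follicles of 7 mice, so the pool was a block in the comparisons of doses. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with 8 residual degrees of freedom for the AMH comparisons. The vehicle arrays of 24 h were compared with those of 12 h without a block, from the 6 vehicle arrays alone. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and the threshold was 0.05. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

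Gene lists were written from general knowledge, and those with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01. Each gene was represented by its tested probe set with the highest mean (11238 genes), and p-values were adjusted over the lists of a comparison. The lists were SMAD1/5/9 targets, AMH and BMP signalling components, granulosa cell markers, FSH-induced genes, LH-induced and cumulus expansion genes, steroidogenesis, cholesterol biosynthesis, theca and interstitial markers, oocyte markers, DNA replication, mitosis, p53 and apoptosis, immediate early genes, heat shock, ER and amino acid stress, hypoxia and glycolysis, extracellular matrix, YAP/TEAD targets, leukocyte, endothelial, red blood cell and ovarian surface epithelium markers, interferon response, oxidative phosphorylation and ribosomal proteins. Camera was repeated with a correlation estimated from the data, and fry was run as a second test.

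Genes named in the text were chosen by a rule set beforehand. It took the 10 largest rises and 10 largest falls past the threshold that moved the same way in every pool (or did not overlap, for the time comparison) and, where fewer than 5 passed, the 5 rises and 5 falls with the smallest unadjusted p. It added fixed genes of the AMH pathway and up to 4 members of each list with the smallest unadjusted p. Not all of these are printed. Alternatives changed the block, the pseudocount (1 or 50), the normalization (quantile or median centring), the filter (none, or only those above the 75th percentile), the variance trend, array weights, the arrays in the fit, the number of probe sets per gene, and left out each pool or vehicle array in turn. Fits without the array that stood apart, and with the 9 arrays of 24 h only, were added after the arrays were examined.

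The methods were tested on simulated data with the spread of these arrays. A log2 change of 1 was called in 1.49% of altered probe sets with the spread of all 18 arrays, 64.2% without the array that stood apart, 76.1% with the 24 h arrays and 14.9% in the time comparison. A change of 2 was called in 34.8%, 95.5%, 92.4% and 78.8%. Of 24 lists shifted by 0.5, 22 were recovered, and 1 of 552 tests of other lists was called. Noise was drawn independently for each gene, so these list counts do not show how often lists of correlated genes are called without a shift. Scanned images and probe-level files were not used here, and some genes are not reported here.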

Results

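Gene expression was measured on 18 Affymetrix mouse arrays, 1 per culture of preantral to small antral follicles from mice of 6 to 8 weeks. The cultures received vehicle, 50 or 200 ng/mL of recombinant anti-Müllerian hormone (AMH, a granulosa cell hormone of the BMP family that acts through AMHR2 and SMAD1/5/9) for 12 or 24 h, in medium with FSH and LH. The 6 groups held 3 arrays each. Each pool of follicles from 7 mice was divided over the 3 doses, which gave 3 pools at each time. The number of arrays limits the precision. The gene lists named below were fixed before the data were examined, and the red blood cell list was not tested, since 2 of its 8 genes were measured.

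One array, AMH 50 ng/mL at 12 h in replicate 3, stood apart from the rest. Its Pearson correlation with the other arrays, across probe sets, lay between 0.458 and 0.494, against 0.813 to 0.984 (median 0.932) among the other 17. Its bacterial hybridisation controls had a mean signal of 28532, against 1441 to 3520 in the others. In the same pool, the AMH 200 ng/mL array had poly-A spike controls at 5494, above the highest value of 1634 outside that pool. Its median correlation with the other arrays was 0.847. The SD of its log2 differences from vehicle was 0.838, against at most 0.402 outside that pool. This second array stayed in the fits without the array that stood apart. All 18 arrays stayed in the tests below, and the counts of probe sets are also given without the array that stood apart, as are the list calls lost without it. Unless said otherwise, each SE of an AMH comparison comes from this 1 fit, not from the pools of that comparison alone. At AMH 200 ng/mL and 24 h the median SE was 0.360 with all arrays and 0.204 without the array that stood apart. Each pool (or vehicle array, for the time comparison) was also left out in turn, and the list calls kept each time in the same direction are named.

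**Figure D1:**
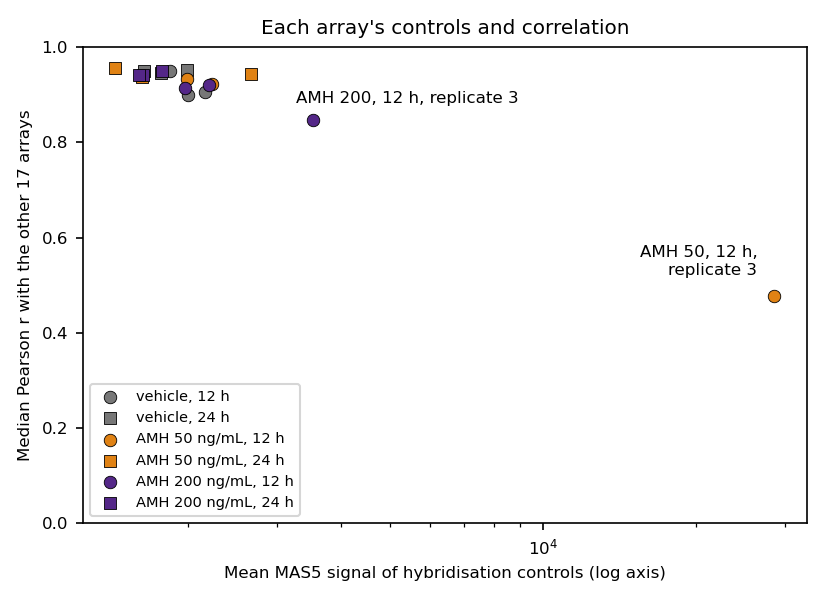
Each point is 1 of the 18 arrays, with the mean MAS5 signal of its hybridisation controls on the x axis (log axis) and its median Pearson correlation with the other 17 arrays on the y axis. Colours give the AMH dose and shapes the time, and the AMH 50 ng/mL array of replicate 3 at 12 h lies at 28532 on the x axis.

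The first comparison asked which transcripts differed between AMH 50 ng/mL and vehicle after 24 h. Oocyte markers fell as a group: all 21 measured markers were lower, with a median log2 change of -0.68. The call was lost with an estimated correlation between genes (adjusted p = 0.0677). Among them, the zona pellucida gene Zp3 differed by -1.58 (log2, SE 0.57, n = 3 pools), from a mean signal of 652 ± 507 (SD) to 272 ± 349. Gdf9, an oocyte growth factor gene, differed by -1.01 (SE 0.40), the oocyte linker histone gene H1f8 by -1.01 (SE 0.33), and Lhx8, an oocyte transcription factor gene, by -0.91 (SE 0.33). None of the 21 passed adjusted over the list alone with all 18 arrays, and 9 did with the 9 arrays of 24 h.

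Macrophage and leukocyte markers also fell as a group at this dose, with 12 of 13 lower and a median of -0.65. With an estimated correlation this call held (adjusted p = 0.00383), but it did not once the array that stood apart was left out (adjusted p = 0.117). Fry called 0 lists in this comparison (smallest adjusted p = 0.175). Tyrobp, the adaptor of myeloid receptors, differed by -1.10 (SE 0.28), from a signal of 211 ± 29.0 to 93.9 ± 43.3, and was the only list member lower adjusted over the list alone. The lysozyme gene Lyz2 differed by -1.08 (SE 0.63) and the leukocyte membrane protein gene Cd53 by -1.01 (SE 0.59). Ovarian surface epithelium markers fell as a group (median -0.76, 12 of 12 estimates below 0), with Muc16 at -1.01 (SE 0.43), mesothelin (Msln) at -0.84 (SE 0.53) and Lgr5 at -0.79 (SE 0.50). The adjusted p was 0.279 with an estimated correlation. The leukocyte pool medians were -0.94, -0.24 and -0.63 and the surface epithelium pool medians -0.22, -1.40 and -0.51.

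Mitosis genes were lower in 29 of 29 members with AMH 50 ng/mL (median -0.31, adjusted p = 0.408 with an estimated correlation), with pool medians of 0.07, -0.45 and -0.64, among them the kinetochore genes Cenpf at -0.75 (SE 0.35) and Cenpe at -0.51 (SE 0.28). DNA replication genes were lower in 26 of 29 (median -0.13, adjusted p = 0.817 with an estimated correlation, and a median of -0.00261 without replicate 2). Extracellular matrix genes rose as a group (median 0.18, 21 of 24 higher), as did theca and interstitial markers (median 0.20, 11 of 14 higher), and both had an adjusted p of 0.573 with an estimated correlation. The theca medians of the 3 pools were 0.79, 0.09 and -0.06, and without replicate 1 both rises were lost. Of the 7 list calls of this comparison, 4 were kept with each pool left out (oocyte, mitosis, leukocyte and surface epithelium). The collagen gene Col1a1, a member of both, stood at 0.73 (SE 0.67). The SMAD1/5/9 targets did not pass (median 0.06, adjusted p = 0.537), nor did the granulosa cell markers (median -0.20, adjusted p = 0.0503). Amhr2, the gene of the AMH receptor, differed by -0.19 (SE 0.73).

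In the test of single probe sets (limma), 0 of 22518 passed at AMH 50 ng/mL and 24 h, and 157 had an unadjusted p under 0.05, where chance gives 1125.9. Without the array that stood apart the count was also 0, with 607 under that unadjusted p. With the 24 h arrays only, 1 probe set passed: Slc18a2, the vesicular monoamine transporter gene, at -1.24 (SE 0.13, adjusted p = 0.0395, lower in 3 of 3 pools), named here after its value was seen. The rises and falls with the smallest unadjusted p, which did not pass, included Cdo1, a cysteine dioxygenase gene, at -1.11 (SE 0.29), the condensin gene Ncapg at -0.78 (SE 0.21), the potassium channel gene Kcnk15 at 1.05 (SE 0.32) and the kinase gene Mapk13 at 0.73 (SE 0.29). The oocyte medians of the 3 pools were -0.08, -0.68 and -1.23, so that the change was far smaller in replicate 1.

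With AMH 200 ng/mL after 24 h, macrophage and leukocyte markers fell as a group against vehicle (median -0.76, 13 of 13 estimates below 0). This call held with an estimated correlation (adjusted p = 0.000343, and 0.0297 without the array that stood apart). It did not hold with fry, which called 0 lists in this comparison (smallest adjusted p = 0.0551). Tyrobp differed by -0.99 (SE 0.28, n = 3 pools), Cd53 by -1.09 (SE 0.59), and the complement gene C1qc by -0.97 (SE 0.47). Ovarian surface epithelium markers fell as a group (median -0.66, 12 of 12 estimates below 0), with Muc16 at -0.92 (SE 0.43) and Lrrn4 at -0.92 (SE 0.55), and had an adjusted p of 0.317 with an estimated correlation. Their pool medians were -0.46, -1.21 and -0.20, and the median was -0.36 without replicate 2. Oocyte markers did not pass at this dose (median 0.01, with the test's direction lower, adjusted p = 0.969).

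SMAD1/5/9 target genes, the direct readout of AMH and BMP receptors, rose as a group (median 0.18, 12 of 16 higher), with an adjusted p of 0.317 with an estimated correlation. Smad6, an inhibitory SMAD induced by this pathway, stood at 0.64 (SE 0.43) and Id3, an inhibitor of bHLH transcription factors, at 0.36 (SE 0.30), each higher in 3 of 3 pools. Other fixed targets were mixed over the 3 pools, with Smad7 at -0.14, -0.56 and 0.52 and Id1 at 0.20, -0.15 and 0.38. FSH-induced granulosa genes rose as a group (median 0.17, adjusted p = 0.44 with an estimated correlation), though 7 of 16 were lower. LH-induced and cumulus expansion genes fell (median -0.15, 14 of 16 lower), with the neuropeptide gene Adcyap1 at -1.03 (SE 0.60), the prostaglandin synthase gene Ptgs2 at -0.87 (SE 0.64) and the EGF-like factor gene Btc at -0.74 (SE 0.65). Their adjusted p was 0.478 with an estimated correlation.

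Theca and interstitial markers fell at this dose (median -0.21, 11 of 14 lower, pool medians -0.30, 0.12 and -0.60), and steroidogenesis genes had a median of -0.07 and a mean of -0.29, with 9 of 12 lower. The adjusted p with an estimated correlation was 0.44 for theca and 0.478 for steroidogenesis. Cyp17a1, the androgen-forming enzyme of theca cells and a member of both lists, differed by -1.65 (SE 0.78), from a signal of 206 ± 199 to 33.2 ± 2.10. The lower signal lay near the median signals of those arrays (26.4 to 36.6), so that the size of this change depends on the value added. Akr1c18, which inactivates progesterone, differed by -1.24 (SE 0.99) and Star, the cholesterol carrier of mitochondria, by -0.40 (SE 0.54, lower in 3 of 3 pools). Hypoxia and glycolysis genes fell (median -0.14, 21 of 22 lower, adjusted p = 0.44 with an estimated correlation), with Ndrg1 at -0.77 (SE 0.49) and Vegfa at -0.42 (SE 0.35). Mitosis (median -0.14), DNA replication (-0.11), interferon response (-0.19) and ribosomal protein genes (-0.11) were also lower, with adjusted p of 0.514, 0.484, 0.478 and 0.514 with an estimated correlation. The interferon call was lost without the array that stood apart (adjusted p = 0.0515), and the ribosomal median was 0.00877 without replicate 2. Of the 12 list calls of this comparison, 3 were kept with each pool left out (LH-induced, leukocyte and surface epithelium), and the SMAD call was lost without replicate 3.

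Among single probe sets at AMH 200 ng/mL and 24 h, limma called 0 of 22518, with 48 at an unadjusted p under 0.05 (374 without the array that stood apart and 981 with the 24 h arrays only, each with a count of 0). Names with the smallest unadjusted p, which did not pass, included Saa3, an acute-phase protein gene, at -1.76 (SE 0.37), the interferon gamma receptor gene Ifngr2 at -1.19 (SE 0.26), the chemokine gene Ccl6 at -1.12 (SE 0.37) and the hyaluronidase gene Cemip at 0.98 (SE 0.38). Saa3 went from a signal of 200 ± 23.2 to 48.7 ± 15.5.

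**Figure D2:**
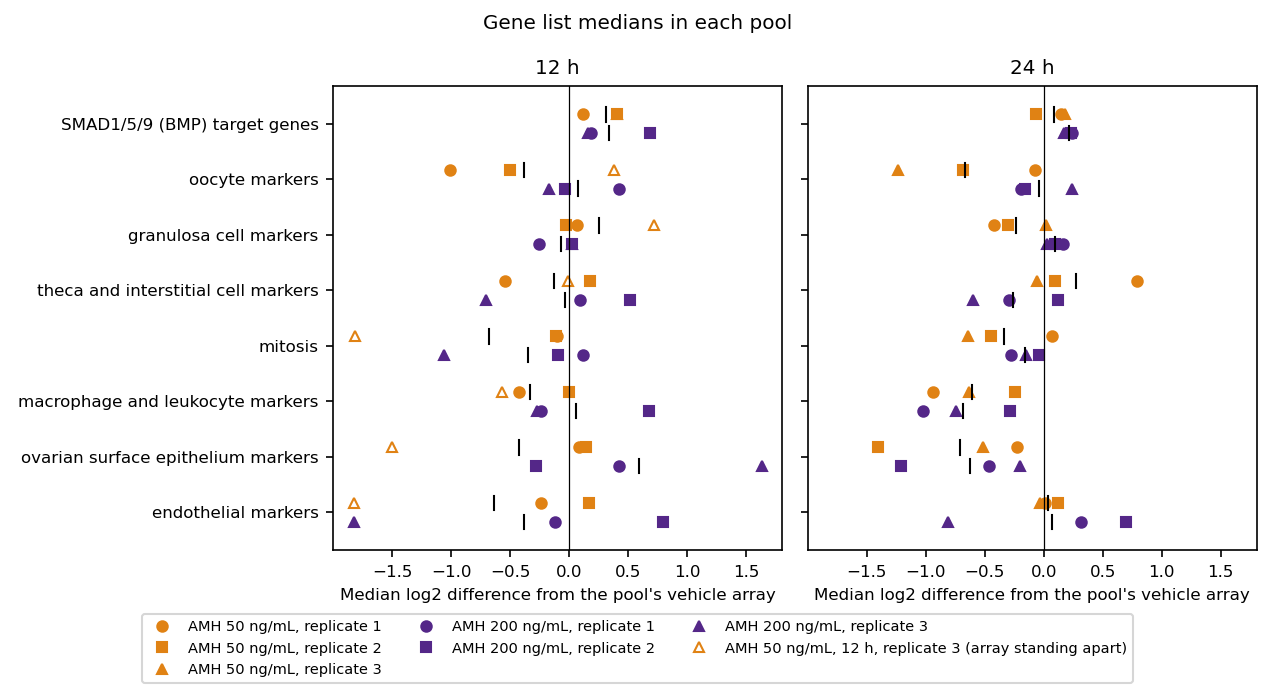
Each symbol is the median, over the genes of a list, of the log2 difference between an AMH array and the vehicle array of its pool (x axis), at 12 h (left) and 24 h (right). Shapes give the replicate, black ticks the mean of the 3 pools, and the open triangle the array that stood apart, which the 12 h means include.

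The 2 doses were compared directly at 24 h to ask which groups depended on dose. Oocyte markers were higher with 200 than with 50 ng/mL (median 0.75, 20 of 21 higher), though in replicate 1 the list median against vehicle was -0.191 with 200 and -0.078 with 50 ng/mL, while the median of the differences of the members was 0.105. None of the 10 list calls of this comparison held with an estimated correlation (smallest adjusted p = 0.168), and 4 were kept with each pool left out (oocyte, LH-induced, cholesterol biosynthesis, and hypoxia and glycolysis). Among the oocyte genes were Zp3 at 1.61 (SE 0.57) and H1f8 at 1.00 (SE 0.33). Granulosa cell markers (median 0.21), AMH and BMP signalling components (0.13) and mitosis genes (0.08) were also higher, with the activin subunit gene Inhba at 1.19 (SE 0.83) and follistatin (Fst) at 0.73 (SE 0.49). Theca markers (median -0.54), LH-induced genes (-0.28), extracellular matrix (-0.26), hypoxia and glycolysis (-0.22), cholesterol biosynthesis (-0.21, 20 of 20 lower) and steroidogenesis (-0.21) were lower with 200 ng/mL, with Ndrg1 at -1.40 (SE 0.49) and the matrix proteoglycan gene Lum at -1.16 (SE 0.52).

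Fry, which asks whether a list moves one way, called 1 list between the doses, the AMH and BMP components (adjusted p = 0.0329). Limma called 0 of 22518 probe sets between the doses at 24 h, with 186 at an unadjusted p under 0.05 (938 without the array that stood apart and 1987 with the 24 h arrays only, where the count was also 0). Leukocyte markers did not differ between the doses (median -0.06, adjusted p = 0.145).

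After 12 h with AMH 200 ng/mL, SMAD1/5/9 targets rose as a group against vehicle (median 0.22, 11 of 16 higher), with an adjusted p of 0.317 with an estimated correlation. Smad6 stood at 0.93 (SE 0.43, n = 3 pools), from a signal of 98.9 ± 18.0 to 225 ± 122, with Id3 at 0.46 (SE 0.30), Smad7 at 0.50 (SE 0.59) and Id1 at 0.29 (SE 0.31), all 4 higher in 3 of 3 pools. Surface epithelium markers, lower at 24 h, were higher here (median 0.48, 12 of 12 higher, adjusted p = 0.542 with an estimated correlation), with pool medians of 0.42, -0.28 and 1.63. Hypoxia and glycolysis genes fell (median -0.27, adjusted p = 0.656 with an estimated correlation, lost without the array that stood apart at adjusted p = 0.0576), with the lactate transporter gene Slc16a3 at -1.61 (SE 0.43), the kinase gene Pdk1 at -1.18 (SE 0.43) and Vegfa at -0.91 (SE 0.35).

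Mitosis genes fell at 12 h with AMH 200 ng/mL (median -0.28, 25 of 29 lower), as did endothelial markers (median -0.43, 11 of 13 lower, lost without the array that stood apart at adjusted p = 0.136), with the VEGF receptor gene Flt1 at -1.16 (SE 0.54) and Pecam1 at -1.10 (SE 0.55). Their adjusted p with an estimated correlation was 0.663 and 0.771, and without replicate 3 of 12 h their medians were 0.04 and 0.17. Heat shock genes (median 0.23, 12 of 12 higher), ribosomal protein genes (0.34) and oxidative phosphorylation genes (0.11) rose, with adjusted p of 0.317, 0.404 and 0.404 with an estimated correlation. Limma called 0 of 22518 probe sets, with 517 at an unadjusted p under 0.05 and 2565 without the array that stood apart, where the count was also 0. The rises and falls with the smallest unadjusted p, which did not pass, included Castor2 at -1.07 (SE 0.27), Mpp2 at -1.04 (SE 0.27), Zfhx3 at 1.05 (SE 0.33) and Slc4a11 at 0.91 (SE 0.26). Without replicate 3 of 12 h the SMAD targets (median 0.37) and the hypoxia genes (median -0.52) still passed, and the other 6 lists did not. The SMAD call was lost without replicate 2 (median -0.04) and the hypoxia call without replicate 1 (median 0.10), so that none of the 8 was kept with each pool left out.

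For AMH 50 ng/mL against vehicle at 12 h, SMAD1/5/9 targets had a median of 0.19 (adjusted p = 0.274 with an estimated correlation), with Smad6 at 1.30 (SE 0.43) and Id1 at 0.86 (SE 0.31). These values drop to 0.60 (SE 0.28) and 0.39 (SE 0.15) without the array that stood apart, and the list then did not pass (median 0.02). Granulosa markers (0.27), immediate early genes (0.30) and ribosomal protein genes (0.30) were higher and mitosis (-0.64) and cholesterol biosynthesis genes (-0.85) lower as groups, beside a median of -0.29 over all genes. The adjusted p with an estimated correlation was 0.274 for granulosa markers and immediate early genes, 0.595 for ribosomal proteins, and 0.868 for mitosis and cholesterol biosynthesis. Without the array that stood apart the median over all genes was -0.04, cholesterol biosynthesis (median -0.01), granulosa markers (0.09) and immediate early genes (0.11) no longer passed either, so that 2 of the 6 lists kept their call (mitosis, at a median of -0.34, and ribosomal proteins), and oocyte markers were lower, with a median of -0.81. Without all 3 arrays of that pool these 2 calls were lost too. In that fit 2 lists passed, of which 1 was by name among the 6.

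Limma called 0 of 22518 probe sets for AMH 50 ng/mL at 12 h, with 2436 at an unadjusted p under 0.05 and 1285 without the array that stood apart (count also 0). Among named genes, the smallest unadjusted p belonged to Pdzd8 at -1.75 (SE 0.35), Wdr70 at -2.02 (SE 0.45) and Pcnt at -1.22 (SE 0.29). Next came Gdf10, a BMP family member, at -2.25 (SE 0.53, and -1.48 without the array that stood apart), and Slc18a2 at -1.86 (SE 0.44). None of these passed. Between the 2 doses at 12 h no list passed, 0 probe sets were called by limma and 2546 had an unadjusted p under 0.05 (1273 without the array that stood apart). Without that array 6 lists passed in that comparison.

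**Figure D3:**
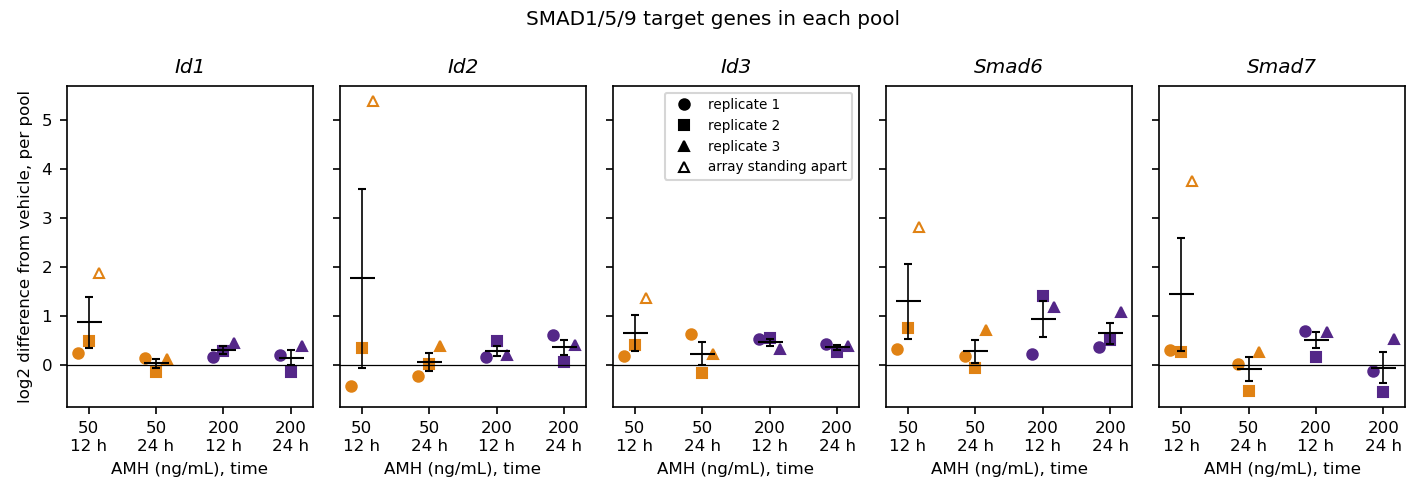
The log2 difference between each AMH array and the vehicle array of its pool (y axis) is shown for the 5 fixed SMAD1/5/9 target genes, by dose and time (x axis). Shapes give the replicate, the open triangle is the array that stood apart, and the bars are the mean ± SE of the 3 pools.

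Averaged over both times, AMH 200 ng/mL left SMAD1/5/9 targets higher as a group (median 0.19, 13 of 16 higher, list median above 0 in 6 of 6 pools), with an adjusted p of 0.056 with an estimated correlation. Smad6 stood at 0.79 (SE 0.30), Id3 at 0.41 (SE 0.22) and Id2 at 0.32 (SE 0.65), each higher in 6 of 6 pools. The Id2 differences in these pools ran from 0.06 to 0.61. Its SE takes in the AMH 50 ng/mL array that stood apart, where Id2 differed by 5.41. Leukocyte markers were lower (median -0.39, adjusted p = 0.0439 with an estimated correlation), with the complement gene C1qc at -0.73 (SE 0.33), and so were hypoxia and glycolysis genes (median -0.22, adjusted p = 0.399 with an estimated correlation), with Slc16a3 at -1.03 (SE 0.30, lower in 6 of 6 pools). AMH 50 ng/mL left oocyte markers lower (median -0.59, 21 of 21 lower, adjusted p = 0.474 with an estimated correlation), with H1f8 at -0.85 (SE 0.23) and Nobox, an oocyte transcription factor gene, at -0.82 (SE 0.27). Slc18a2 stood at -1.55 (SE 0.31), lower in 6 of 6 pools.

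With AMH 200 ng/mL, 9 lists passed over both times, also mitosis (-0.28), cholesterol biosynthesis (-0.18), DNA replication (-0.12) and endothelial markers (-0.25) lower, ribosomal protein (0.11) and heat shock genes (0.09) higher. With an estimated correlation the leukocyte call held (adjusted p = 0.0439, but 0.392 without the array that stood apart), and the 7 lists other than this one and the SMAD targets had an adjusted p of 0.399 to 0.683. At either dose fry called 0 lists over both times (smallest adjusted p = 0.426 for AMH 200 and 0.0678 for AMH 50 ng/mL). With AMH 50 ng/mL 8 lists passed, also mitosis (-0.46), DNA replication (-0.25), leukocyte (-0.54) and surface epithelium markers (-0.56) lower, ribosomal protein (0.15), immediate early (0.24) and SMAD targets (0.02) higher, beside a median of -0.15 over all genes. None of the 8 held with an estimated correlation (smallest adjusted p = 0.247). Without the array that stood apart 7 lists passed at each dose. The calls of DNA replication and endothelial markers were lost for AMH 200 ng/mL, and those of SMAD targets, immediate early genes and surface epithelium markers for AMH 50 ng/mL. Without replicate 3 of 12 h the endothelial and ribosomal medians of AMH 200 ng/mL were 0.0796 and -0.0198. With each pool left out in turn, 5 to 11 lists passed for AMH 200 ng/mL and 4 to 8 for AMH 50 ng/mL. Only the leukocyte call was kept each time for AMH 200 ng/mL, and those of oocyte markers and mitosis for AMH 50 ng/mL. Limma called 0 probe sets at either dose, with 667 (AMH 50) and 131 (AMH 200) at an unadjusted p under 0.05, and 1058 and 767 without the array that stood apart (count also 0).

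Whether the effect of AMH differed between 12 and 24 h was tested as an interaction. Surface epithelium markers (median -1.08, 12 of 12 lower), leukocyte markers (-0.53), ribosomal protein (-0.45), heat shock (-0.33), immediate early (-0.27), oxidative phosphorylation (-0.22) and interferon genes (-0.22) responded less, or more negatively, at 24 h with AMH 200 ng/mL. The leukocyte difference held with an estimated correlation (adjusted p = 0.0223, and 0.26 without the array that stood apart), and the other 6 had an adjusted p of 0.276 to 0.745. With AMH 50 ng/mL 7 lists differed between the times, 0 with an estimated correlation (smallest adjusted p = 0.189). Without the array that stood apart 8 lists passed for AMH 50 ng/mL, 4 of them among the 7, and 6 for AMH 200 ng/mL, where the interferon call was lost (its median was 0.18 without replicate 1 of 12 h). With each pool left out, 1 of the 7 calls was kept for AMH 50 ng/mL (granulosa markers) and 3 of the 7 for AMH 200 ng/mL (leukocyte, surface epithelium and ribosomal proteins). Limma called 0 probe sets in both interactions, with 409 (AMH 50) and 257 (AMH 200) at an unadjusted p under 0.05, and 733 and 1618 without the array that stood apart (count also 0).

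Across all 22518 probe sets, which are not independent replicates, the log2 changes at 12 and 24 h had a Pearson r of 0.011 (Spearman rho 0.011) with AMH 50 ng/mL and -0.189 (rho -0.205) with AMH 200 ng/mL. When the signs of the pools' differences were flipped in all 64 ways, 60 and 20 flips gave an r as far from 0.

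The comparison of vehicle cultures at 24 h with those at 12 h asked how cultures differed with time. Granulosa cell markers rose as a group (median 0.84, 15 of 16 higher). With an estimated correlation none of the 9 list calls of this comparison held (smallest adjusted p = 0.244). All but those of heat shock and of ER and amino acid stress genes were kept with each vehicle array left out. The FSH receptor gene Fshr rose by 2.43 (SE 0.45, n = 3 arrays against 3), from a signal of 15.8 ± 18.8 (SD), below the array medians, to 149 ± 67.9, and Foxl2, a transcription factor gene of granulosa identity, by 1.05 (SE 0.14). Adjusted over the list alone, 9 rose, also Hsd17b1, which forms estradiol, by 1.99 (SE 0.44) and the inhibin subunit gene Inhbb by 1.12 (SE 0.23). Steroidogenesis genes (median 0.53, 12 of 12 higher, 6 rose adjusted over the list alone) and FSH-induced genes (0.51, 12 of 16 higher, with Mro up by 1.62, SE 0.24) rose as groups too.

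LH-induced and cumulus expansion genes fell (median -0.97, 12 of 16 lower), which, like the other falls given here for lists, did not hold with an estimated correlation, with the hyaluronan receptor gene Cd44 at -1.72 (SE 0.19), Btc at -2.17 (SE 0.33) and the EGF-like ligand gene Ereg at -1.64 (SE 0.27), each past the threshold. Immediate early genes fell as a group (median -0.76, 20 of 20 estimates below 0), with Egr3 at -2.02 (SE 0.26), Fos at -1.74 (SE 0.29), Fosb at -1.53 (SE 0.29) and Klf4 at -1.11 (SE 0.21) past the threshold. Mitosis genes fell as a group (median -0.93, 29 of 29 estimates below 0), with the ubiquitin-conjugating enzyme gene Ube2c at -1.16 (SE 0.22), and 19 passed adjusted over the list alone. DNA replication genes (median -0.45, 28 of 29 lower), heat shock genes (-0.25, 12 of 12 lower) and ER and amino acid stress genes (-0.19, 16 of 19 lower) fell as well. SMAD targets did not pass as a list (median 0.12), though Id2 rose by 0.96 (SE 0.18), and neither did oocyte (0.10), endothelial (-0.66), YAP/TEAD (-0.02) or p53 and apoptosis genes (-0.06).

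The largest single rises, on the log2 scale with 16 added, were Prrt4, by 3.42 (SE 0.29), whose second probe set did not pass (0.22, SE 0.25), the lipid droplet protein gene Plin5, by 3.24 (SE 0.41), Dpysl4, by 3.09 (SE 0.28), N4bp2l1, by 3.03 (SE 0.55), and the semaphorin receptor gene Plxnc1, by 2.96 (SE 0.47). Pgbd5 (2.80), Cmtm2a (2.78), Enpp3 (2.77), the anion transporter gene Slc26a7 (2.67) and the troponin gene Tnni3 (2.66) followed. The second probe sets of N4bp2l1 and of Foxl2, Klf4 and Id2, named above, had the same sign but did not pass either. The largest falls were the neuropeptide gene Nts at -3.57 (SE 0.33), from a signal of 1050 ± 561 to 67.5 ± 12.3, the tight junction gene Cldn2 at -2.89 (SE 0.50), Ramp3 at -2.88 (SE 0.39), the CRH-binding protein gene Crhbp at -2.73 (SE 0.28) and Nmu at -2.65 (SE 0.45). Sh2d5 (-2.38), Sprr1a (-2.34), Btc (-2.27 at a second probe set), the CSF1 receptor gene Csf1r (-2.27) and the cytokine gene Il11 (-2.25) came next. The mean signals of Prrt4, Plin5 (23.8) and Cmtm2a (8.20) at 12 h and of Cldn2 (4.99), Crhbp (5.78) and Nmu (8.09) at 24 h lay below or near the median signal of the vehicle arrays (23.2 to 31.8), so that the sizes and the order of these changes depend on the value added. Over the alternatives Prrt4 ran from 2.54 to 4.41, and Cldn2 and Nmu did not pass with 50 added. Prrt4 passed in 14 of 17 alternatives, Foxl2 and Cd44 each in 13 of 18, and Egr3 in 13 of 17. Fos passed in 11 of 18, Ereg in 9 of 18, Id2 in 8 of 18 and Fshr in 8 of 17. Klf4 and Ube2c each passed in 7 of 18, and Fosb in 6 of 17. The macrophage and leukocyte list itself did not pass (median 0.21, mean -0.11, test direction lower), with Tyrobp at 0.91 (SE 0.23) and Lyz2 at 1.42 (SE 0.39).

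**Figure D4:**
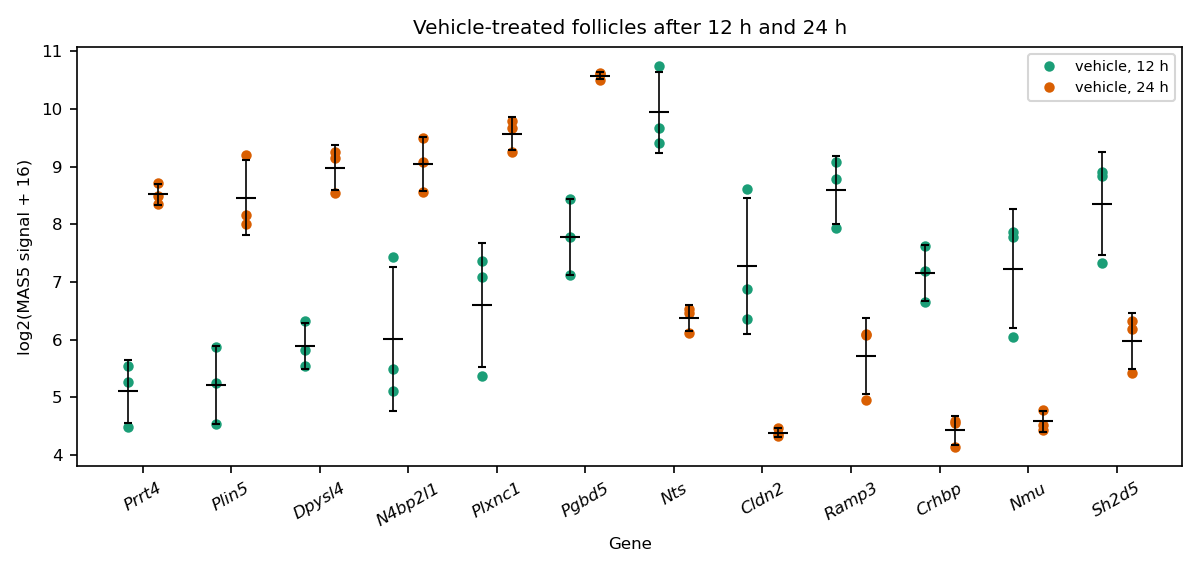
Points are log2(MAS5 signal + 16) (y axis) of the 3 vehicle arrays at 12 h and the 3 at 24 h, for the 6 genes with the largest rise and the 6 with the largest fall past the threshold (x axis), and bars are the mean ± SD. The 12 h and 24 h arrays do not overlap in any of the 12 genes, because the rule that chose these genes required it.

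Limma called 292 of 22518 probe sets between the times, 198 higher (148 genes) and 94 lower (73 genes), with 4180 at an unadjusted p under 0.05. With the vehicle arrays paired by replicate number, since their deviations from the group means correlated across the times (r of 0.318, 0.261 and 0.207 across probe sets), the count was 642, of which 289 were shared with the 292. The pairing gave 12 lists instead of 9, also endothelial markers (median -0.66), extracellular matrix (-0.21) and ribosomal protein genes (-0.12) lower. Fry called 1 list, the LH-induced genes (adjusted p = 0.0186). The design notes call arrays comparable only within an experiment, and the cultures of 12 and 24 h were separate experiments. The count was 0 without replicate 2 or replicate 3 of 24 h, 1 without replicate 1 of 24 h, 35 without replicate 2 of 12 h and 555 without replicate 3 of 12 h.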

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

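Chosen after the result was seen were the tests of the array that stood apart, of the leukocyte and surface epithelium markers, and of a dose effect on the oocyte markers. The other 2 oocyte tests and all counts over other splits were set beforehand.

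Among control probe sets, which the comparisons do not use, 2 arrays of the third 12 h pool lay above the vehicle arrays by more than 1.5 times. The AMH 50 ng/mL array had a mean signal of 28532 for bacterial hybridisation controls and 17457 for poly-A spike controls, and the AMH 200 ng/mL array 3520 and 5494. Hybridisation controls are added at a fixed amount, so that little labelled target scales them up, and in the AMH 50 ng/mL array they were 14.2 times the mean of the others. That value was seen before its bound was set, so it does not count for this explanation. RNA degradation stays open. The same controls missed its bound, but degraded RNA can also leave little target, so they cannot decide. The Gapdh 3' to 5' ratio was 2.53, against 1.16 to 1.73 in the other arrays. An effect of AMH 50 ng/mL is argued against by the other 2 pools, whose SD of the log2 difference from vehicle was at most 0.400 against 1.97. Too little target, with or without RNA degradation, stays open as the source of this array's profile.

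Leukocyte and surface epithelium markers were lower with both doses at 24 h, with Tyrobp at -1.10 and -0.99 and Muc16 at -1.01 and -0.92. Both doses were set against the same vehicle arrays, so that their falls do not replicate each other. Vehicle at 24 h against 12 h had the surface epithelium genes Upk3b at 2.53 (past the threshold), Lrrn4 at 1.38, Muc16 at 1.21 and Krt18 at -0.67. The second probe set of Upk3b did not pass. A single vehicle array with high levels could lower only its own pool. The bound against it, a median below -0.2 in every pool by more than its SE, was missed. The highest median was -0.205 (SE over members 0.106, surface epithelium markers at AMH 200 ng/mL in replicate 3). With 1 pool left out, the medians of both lists at both doses still ran from -0.97 to -0.36 (SE over members up to 0.17). These values argue against 1 high vehicle array as the whole source. They were seen before this was asked, and the SE over members takes no account of correlation between members. Less carry-over of all non-follicle cells stays open at both doses. Endothelial markers did not fall with AMH 50 ng/mL (median 0.0862, SE over pools 0.0459), but follicles with a theca can hold endothelial cells of their own. With AMH 200 ng/mL the spread was too wide to tell (0.00841, SE 0.452). The test was split by dose after its values were seen. An effect of AMH on these cells at both times stays open too (0.48, SE 0.56, at AMH 200 ng/mL and 12 h), as does a candidate cause that was not tested, uneven numbers of these cells in the divided pools.

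Oocyte markers were lower with AMH 50 ng/mL at 24 h, with Zp3 at -1.58 and Gdf9 at -1.01. The pool with the highest poly-A controls, a sign of little RNA, is argued against as the whole cause. The medians of the other 2 pools were at most -0.680 (SE over members 0.075), while its own was -0.078. That SE lies within 1 pool and takes no account of correlation between members. Fewer or smaller oocytes among the follicles taken stay open as a source. The bound was met, with 100% of the 21 markers lower. That count restates the pattern, and an effect of AMH on oocyte transcripts could give it too, so it cannot decide. An effect that grows with dose stays open: the marker median against vehicle was higher at 200 than at 50 ng/mL by 0.626 (SE 0.460) over the 3 pools, but by -0.114 in replicate 1, where the median of the differences of the members was 0.105. An effect of AMH at 50 ng/mL alone stays open too and was not tested apart from this.

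The response to AMH 50 ng/mL differed between 24 and 12 h by the interaction test in 7 lists, with medians of -0.48 for granulosa markers, 0.98 for cholesterol biosynthesis, -0.39 for oocyte markers, -0.51 for immediate early genes, 0.73 for extracellular matrix, -0.0342 for leukocyte markers and -0.31 for ribosomal proteins, beside a median of 0.26 over all genes. None of the 7 held with an estimated correlation (smallest adjusted p = 0.189), and 4 passed without the array that stood apart. The response to AMH 200 ng/mL differed in 7 lists, with medians of -0.27 for immediate early genes, -0.33 for heat shock, -0.53 for leukocyte markers, -1.08 for surface epithelium markers, -0.22 for interferon response, -0.22 for oxidative phosphorylation and -0.45 for ribosomal proteins. Of these, the leukocyte difference held with an estimated correlation (adjusted p = 0.0223, and 0.26 without the array that stood apart), and 6 passed without the array that stood apart. The values of AMH 50 ng/mL include the array that stood apart.

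Other splits of the same arrays were counted. For the dose comparisons they reassigned the doses across pools, while the fit kept the pool block. They are not swaps within a pool, so their shares are no reference for the paired design. For the comparisons within a time there were 10 splits, too few for a share under 0.05. The counts of probe sets past the threshold were 0 for AMH 50 ng/mL, AMH 200 ng/mL and AMH 200 against 50 ng/mL at 12 h, with highest other splits of 5712, 0 and 4184. Among the comparisons within a time, 5712 and 4184 arose only where the arrays split include the AMH 50 ng/mL arrays of 12 h. The array that stood apart is among them, and whether it alone gave these counts was not tested. At 24 h all 3 real counts were 0 and the highest other split 0. A count of 0 is reached by every split (10 of 10), so that these splits test nothing. The time comparison had 292 against a highest other of 0, with 1 of 10 splits as large.

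For gene lists within a time, the real counts and highest other splits were 6 and 10 (AMH 50 ng/mL, 12 h, 4 of 10 splits as large), 8 and 9 (AMH 200 ng/mL, 12 h, 2 of 10), 0 and 9 (AMH 200 against 50 ng/mL, 12 h, 10 of 10), 7 and 9 (AMH 50 ng/mL, 24 h, 6 of 10), 12 and 15 (AMH 200 ng/mL, 24 h, 2 of 10), 10 and 12 (AMH 200 against 50 ng/mL, 24 h, 5 of 10), and 9 and 11 (time, 8 of 10). For the means over both times, 100 splits were drawn. The probe set counts were 0 with a highest other of 0 at both doses, which all 100 splits reach by construction. The list counts were 8 with a highest other of 10 for AMH 50 ng/mL (15 of 100) and 9 with a highest other of 13 for AMH 200 ng/mL (25 of 100). Chance cannot be excluded for them, and these splits, which ignored the pairing within pools, cannot decide it.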

How the results depend on the processing

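Fits without the array that stood apart and with the 9 arrays of 24 h only were chosen after the arrays were examined, and the other alternatives before. The AMH comparisons called 0 probe sets with limma under each alternative except these. Array weights gave 88 (AMH 50 ng/mL) and 76 (AMH 200 ng/mL) at 12 h, 1461 (AMH 50 ng/mL), 21 (AMH 200 ng/mL) and 934 (AMH 200 against 50 ng/mL) at 24 h, 773 (AMH 50 ng/mL) and 6 (AMH 200 ng/mL) for the means, and 17 and 11 for the time differences of AMH 50 and 200 ng/mL. Their estimation did not reach its convergence tolerance, and the weights ran from 0.00188 (AMH 50 ng/mL, 12 h, replicate 3) to 57.5 (AMH 50 ng/mL, 24 h, replicate 3). For AMH 50 ng/mL at 24 h, using only the arrays compared gave 10 (1 higher, 9 lower) and the 24 h arrays only gave 1. Leaving out each pool gave 0 to 2 for AMH 50 ng/mL at 12 h (2 without 12 h replicate 2) and 0 to 1 for AMH 200 against 50 ng/mL at 12 h (1 without 12 h replicate 2). The spread limits these counts: within a time the median SE was 0.360 with all arrays, 0.204 to 0.239 without the array that stood apart and 0.160 with the 24 h arrays. The cause of the other changes was not tested.

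The 292 probe sets of the time comparison became 642 with a replicate block that paired the vehicle arrays (289 shared), 131 with pseudocount 1, 60 with no filter, 132 above the 75th percentile, 778 with array weights, 165 with 1 probe set per gene, 34 with all 18 arrays and pools as a random block, and 627 with the mean of each pool (182 shared), which mixes in AMH arrays by construction. Leaving out a vehicle array gave 0 to 555: 1, 0 and 0 without 24 h replicates 1, 2 and 3, and 343, 35 and 555 without 12 h replicates 1, 2 and 3. Fewer arrays leave fewer degrees of freedom, and the cause of the differences between them was not tested.

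Of 264 list tests 83 passed with the preset correlation, 4 with an estimated one and 2 with fry. Without the array that stood apart, the lists past the threshold went from 6 to 8 (AMH 50 ng/mL), 8 to 9 (AMH 200 ng/mL) and 0 to 6 (AMH 200 against 50 ng/mL) at 12 h, and from 7 to 9, 12 to 13 and 10 to 12 at 24 h. Of these, 2, 6 and 0 at 12 h and 7, 11 and 10 at 24 h were lists past the threshold with all arrays. For AMH 50 and 200 ng/mL, the means went from 8 to 7 (5 shared) and 9 to 7 (7 shared), and the time differences from 7 to 8 (4 shared) and 7 to 6 (6 shared). The agreement of changes between the times ran from r = -0.0156 to 0.152 for AMH 50 ng/mL over the left-out pools (0.152 without 12 h replicate 3) and from -0.239 to -0.0668 for AMH 200 ng/mL (-0.0894 without 12 h replicate 3, -0.0668 without 24 h replicate 2). No change past the threshold among the named genes reversed under an alternative.

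Some list medians changed sign, or the test of the list changed direction against the other genes. With quantile normalization, ribosomal proteins were at -0.31 for AMH 50 ng/mL at 12 h, -0.12 for its mean and 0.26 for its time difference. Without the array that stood apart, cholesterol biosynthesis was at -0.0110 for AMH 50 ng/mL at 12 h, -0.18 for AMH 200 against 50 ng/mL at 12 h and 0.0670 for the mean of AMH 50 ng/mL, surface epithelium markers at 0.39 for AMH 50 ng/mL at 12 h, theca markers at 0.36 for AMH 200 against 50 ng/mL at 12 h, and oocyte markers at 0.0237 for the time difference of AMH 50 ng/mL. When each pool or vehicle array was left out in turn, medians also changed sign or side, and the cause was not tested. For AMH 50 ng/mL at 12 h, the medians ran, for cholesterol biosynthesis from -1.40 to 0.12 (0.12 without 12 h replicate 3). For AMH 200 ng/mL at 12 h, the medians ran, for mitosis from -0.61 to 0.0367 (0.0367 without 12 h replicate 3) and endothelial markers from -1.09 to 0.17 (0.17 without 12 h replicate 3). For AMH 200 against 50 ng/mL at 12 h, the medians ran, for theca markers from -0.27 to 0.51 (0.51 without 12 h replicate 3). For AMH 50 ng/mL at 24 h, the medians ran, for theca markers from -0.00478 to 0.42 (-0.00478 without 24 h replicate 1), DNA replication from -0.25 to -0.00261 (-0.00261 without 24 h replicate 2) and ribosomal proteins from -0.28 to 0.24 (0.24 without 24 h replicate 2). For AMH 200 ng/mL at 24 h, the medians ran, for ribosomal proteins from -0.23 to 0.00877 (0.00877 without 24 h replicate 2) and endothelial markers from -0.29 to 0.47 (0.47 without 24 h replicate 3). For AMH 200 against 50 ng/mL at 24 h, the medians ran, for endothelial markers from -0.36 to 0.37 (0.37 without 24 h replicate 3). For the mean of AMH 50 ng/mL, the medians ran, for cholesterol biosynthesis from -0.67 to 0.12 (0.12 without 12 h replicate 3). For the mean of AMH 200 ng/mL, the medians ran, for interferon response from -0.34 to 0.0160 (-0.34 without 12 h replicate 1), endothelial markers from -0.49 to 0.0796 (0.0796 without 12 h replicate 3, -0.09 without 24 h replicate 3), surface epithelium markers from -0.32 to 0.17 (-0.32 without 12 h replicate 3) and ribosomal proteins from -0.0198 to 0.20 (-0.0198 without 12 h replicate 3). For the time difference of AMH 50 ng/mL, the medians ran, for cholesterol biosynthesis from -0.0507 to 1.55 (-0.0507 without 12 h replicate 3), oocyte markers from -0.73 to 0.0465 (-0.001 without 12 h replicate 3), mitosis from -0.31 to 0.55 (-0.31 without 12 h replicate 3) and immediate early genes from -0.54 to 0.0479 (0.0479 without 12 h replicate 3). For the time difference of AMH 200 ng/mL, the medians ran, for interferon response from -0.42 to 0.18 (0.18 without 12 h replicate 1), cholesterol biosynthesis from -0.15 to 0.36 (-0.15 without 12 h replicate 3) and mitosis from -0.21 to 0.44 (-0.21 without 12 h replicate 3). For vehicle at 24 against 12 h, the medians ran, for oocyte markers from -0.93 to 0.77 (-0.93 without vehicle 12 h replicate 3).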

Other observations

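Slc18a2, the gene of the vesicular monoamine transporter, was the only probe set called for AMH 50 ng/mL with the 24 h arrays alone, and it was chosen after its value was seen. Its mean signal at 24 h was 1008 ± 218 (SD, n = 3) in vehicle, 414 ± 73.2 with 50 ng/mL and 751 ± 310 with 200 ng/mL. Amhr2, the AMH receptor gene, differed from vehicle by -0.07 (SE 0.52) with 200 ng/mL over both times, not past the threshold. Between vehicle cultures of 24 and 12 h, 1 of its 3 tested probe sets rose past the threshold, by 1.61 (SE 0.30), while the brightest one, at 0.73 (SE 0.29), did not.

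Both doses at 1 time share their vehicle arrays, which alone makes their changes correlate. Across probe sets, which are not independent replicates, the Pearson r between the doses was 0.532 at 12 h without the array that stood apart (0.427 in simulated data with no effect) and 0.312 at 24 h with all arrays, below the simulated value at that time.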
